A study of Homo sapiens with 9 samples.

How the data were processed

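RNA sequencing of SNU16 cells, a human gastric carcinoma line, was analysed in 9 libraries from 3 groups of 3 replicates: untreated control cells, cells exposed to 7.69 µM 5-fluorouracil (5-FU) and cells exposed to 80 µM hydrogen peroxide (H2O2), all for 24 h, per the labels. Total RNA was made into libraries with the NEBNext Ultra Directional kit, which marks the strand of the RNA, per the labels' protocols. Nothing in the sources used here says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

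The authors deposited FPKM values per transcript, 1 column per library, in a table of 90652 transcripts under 28717 gene identifiers. The table holds mostly transcripts of non-coding classes: long non-coding RNA (lncRNA) transcripts, retained-intron transcripts listed under protein-coding genes, and 475 transcripts assembled from the reads. HISAT2 2.0.5, StringTie and edgeR 3.22.5 and the build GRCh38 are named, without their roles, per the submitters' processing notes. The StringTie version, the annotation release and whether strand entered the quantification are not given in the sources used here. Values of antisense and overlapping genes are therefore uncertain, and a value under a protein-coding symbol is mostly that of listed retained-intron or other non-coding transcripts, not of its mRNA. V29 classes 322 listed transcripts, 138 of them tested, as protein-coding, and the values of NFKB2, KLF4 and LINC03040 include such transcripts. Retained-intron transcripts share exons with the mRNA, and the division of reads between overlapping models can itself differ between libraries.

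Sequencing depth is unknown. The smallest value above 0 was 1e-06 FPKM in every library, far below a single read, so whole reads could not be recovered from the deposited values. No interval that needs counts is given. The listed FPKM summed to between 56096.4 and 60642.1 per library, and 9044 to 9335 genes per library reached 0.5 FPKM.

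The FPKM of all transcripts of a gene identifier were summed, without further scaling. A gene was tested when at least 3 of the 9 libraries reached 0.5 FPKM, which left 9947 genes. By GENCODE V29, an annotation of the same build, 6700 of these were protein-coding genes, 2555 were lncRNA genes, 17 were of other classes and 675 were absent from that release. Transcript classes were taken from V29 by Ensembl identifier for 58221 transcripts of the table, 27758 of them retained-intron. For tested protein-coding genes, the median share of the summed FPKM that came from V29 retained-intron transcripts was 100%.

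Differences were tested on log2(FPKM + 0.5) with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3. All 9 libraries entered 1 fit with 6 residual degrees of freedom and no replicate term. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Log2 differences are on the log2(FPKM + 0.5) scale, which understates changes of genes with low values. The 3 contrasts were 5-FU against control, H2O2 against control and 5-FU against H2O2, the last being the test of whether the 2 treatments differ. Single transcripts (22618 tested) were treated the same way. Single genes of interest were also compared by exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1. Coordinates are those of the deposited table (GRCh38), as the span of a gene's listed transcripts.

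Before the data were examined, the groups, tests, thresholds, 28 gene lists, the processing alternatives and the rule for naming genes were fixed. Lists were tested with camera (inter-gene correlation preset to 0.01), adjusted over 44 tests, that is 22 lists with at least 3 tested genes in the 2 contrasts with control. Camera with an estimated correlation and fry were alternatives. The rule named the 6 genes that rose and the 6 that fell most among those with a symbol, past the threshold, with a mean of at least 2 FPKM in the higher group and no overlap between groups. It added the 3 lncRNA genes that rose and the 3 that fell most, also with a symbol, at a mean of at least 1 FPKM, up to 4 called members of each list or otherwise the 2 most abundant, up to 5 genes higher in each treatment for 5-FU against H2O2, up to 5 called the same way and up to 5 called in opposite ways by both treatments, and the genes of the study's title with their neighbours. Genes named outside this rule are stated to have been chosen after their values were seen.

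The procedure was tested on simulated data with the spread of these libraries and 200 of 9947 genes changed. At a log2 change of 1 it recovered 50% of the changed genes for 5-FU and 49.5% for H2O2. At a log2 change of 2 it recovered 96% and 97.5%.

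Alternatives covered pseudocounts of 0.1 and 1, no filter and a filter at 1 FPKM, median-of-ratios, common-total and quantile scaling, a fit on the 2 groups compared alone, robust moderation, an added minimum log2 difference of 1, a term for the replicate number, and leaving out each library in turn. Others were added after the data were seen: leaving out the assembled transcripts, limma array weights, dropping both treatment libraries numbered 3, testing the lists in 5-FU against H2O2, and adjusting over lncRNA genes alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 from tables made with pandas 2.3.3 and numpy 2.4.6.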

Results

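To look for transcripts involved in the response of gastric cancer cells to chemotherapy and oxidative stress, RNA was sequenced from SNU16 cells, a line established from the ascites of a patient with gastric carcinoma. Cells were left untreated (control), exposed to 7.69 µM 5-FU, an antimetabolite that blocks thymidylate synthase and enters RNA and DNA, or exposed to 80 µM H2O2, a reactive oxygen species, for 24 h, with 3 replicates per group. The values used here are FPKM of transcripts mostly of non-coding classes, and 9947 genes had enough signal to be tested. Transcripts of lncRNA genes made up 15.55% ± 0.16 (SD, n = 3) of the listed FPKM in control, 14.51% ± 0.33 in 5-FU and 14.2% ± 1.03 in H2O2 libraries. Depth is unknown, and the listed FPKM summed to between 56096.4 and 60642.1 per library.

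The 3 control libraries lay close together on the first principal component, at -18.07, -18.72 and -18.67, and the 5-FU libraries lay apart from them at 12.51, 15.78 and 33.28. Replicate 3 of 5-FU stood away from the other 5-FU libraries on that component. On the second component replicate 3 of H2O2 was at -41.86, against -3.4 and -2.39 for the other H2O2 libraries. Correlations between replicates across genes, which are not independent replicates, were 0.935 to 0.936 in control, 0.929 to 0.942 in 5-FU and 0.918 to 0.941 in H2O2, and no library duplicated another.

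**Figure D1:**
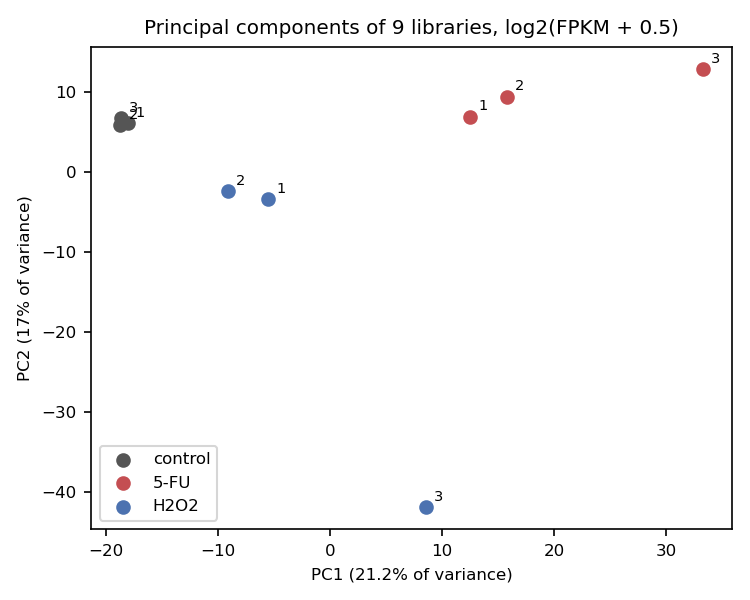
Principal components of log2(FPKM + 0.5) over 9947 genes, with each point a library, coloured by group and numbered by replicate (axes in component units, PC1 21.2% and PC2 17% of variance). The control libraries lie together, and replicate 3 of 5-FU (33.28 on PC1) and replicate 3 of H2O2 (-41.86 on PC2) stand apart from their groups.

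The comparison of 5-FU with control asked which transcripts respond to the drug. Transcripts listed under 3 DNA replication genes, MCM5, MCM10 and CDC45, rose. MCM5, a subunit of the replicative helicase (chromosome 22, 35410409 to 35424501), rose from 5.08 ± 0.424 to 10.7 ± 0.649 FPKM (SD, n = 3 each), a log2 difference of 1.002 (SE 0.14, limma adjusted p = 0.0224). MCM10, which helps to activate that helicase (chromosome 10, 13192491 to 13204526), rose from 1.61 ± 0.0840 to 4.57 ± 0.436 FPKM (log2 difference 1.26, SE 0.18, limma adjusted p = 0.0224). CDC45, another component of the active helicase (chromosome 22, 19479738 to 19520594), rose from 4.04 ± 0.109 to 8.14 ± 0.767 FPKM (log2 difference 0.92, SE 0.14, limma adjusted p = 0.0265). Among lncRNA genes, SNHG7, a host gene of small nucleolar RNAs (chromosome 9, 136721366 to 136728184), fell from 60.2 ± 2.84 to 33.1 ± 4.58 FPKM (log2 difference -0.86, SE 0.13, limma adjusted p = 0.0265). In each of these 4 genes, the 3 5-FU libraries lay outside the range of the 3 controls.

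In all, limma called 77 of 9947 genes in 5-FU, 52 higher and 25 lower, with 1541 genes at an unadjusted p under 0.05 where chance gives 497. The smallest adjusted p was 0.00872. In all 77 the groups did not overlap, as in 2223 of the genes tested, where chance gives 10% of genes. With median-of-ratios scaling the calls were 54 higher and 40 lower. The count depended on the libraries in the fit: it was 1, 1 and 2 without control replicates 1, 2 and 3, and 7, 0 and 3 without 5-FU replicates 1, 2 and 3. Without H2O2 replicates 1, 2 and 3 it was 20, 76 and 88. The median absolute log2 difference of the 77 genes was 1.11 to 1.17 with 1 library left out, against 1.16 with all. The fits without 1 H2O2 library all have the same number of libraries, so that number alone does not account for their unlike counts. Whether the calls without a control or 5-FU library were lost through that library or through the smaller number of libraries was not tested.

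ZGRF1, a DNA helicase, rose from 5.73 ± 0.349 to 15.6 ± 2.39 FPKM (log2 difference 1.36, SE 0.20, limma adjusted p = 0.0224). RECQL4, a helicase of the RecQ family, rose from 1.94 ± 0.555 to 5.35 ± 0.946 FPKM (1.28, SE 0.21, adjusted p = 0.0309), and PKMYT1, a kinase that restrains CDK1 before mitosis, from 2.03 ± 0.481 to 6.98 ± 2.45 FPKM (1.53, SE 0.24, adjusted p = 0.0265). MOGS, the glucosidase that starts the trimming of N-glycans, rose by 1.36 (adjusted p = 0.0484), and EIF2S1, the alpha subunit of a translation initiation factor, by 2.22 (adjusted p = 0.0297), with EIF2S1 at 10.3, 19.9 and 6.05 FPKM in the 3 5-FU libraries. Among genes that fell, RPL14, a ribosomal protein gene, went from 109 ± 11.4 to 22.5 ± 6.37 FPKM (-2.29, SE 0.42, adjusted p = 0.0406) and PIF1, a DNA helicase, from 2.55 ± 0.536 to 0.687 ± 0.198 FPKM (-1.36, SE 0.21, adjusted p = 0.0262). The value of RPL14 varied widely within the H2O2 group, at 46.2, 152 and 41.2 FPKM in replicates 1, 2 and 3, and the cause was not tested. LINC03040, a gene that V29 lists as protein-coding, fell from 9.85 ± 2.96 to 3.76 ± 0.0909 FPKM (-1.25, SE 0.22, adjusted p = 0.0322).

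The largest fitted rise stood under BTD, the biotinidase gene, at 67.1 ± 15.2 FPKM in control and 392 ± 68.3 FPKM in 5-FU (log2 difference 2.55, SE 0.24, limma adjusted p = 0.00872). Of that signal 99.999% came from 2 overlapping assembled transcripts on chromosome 3, named in the table as antisense to the gene. The longer (15657907 to 15738746) was at 379 ± 66.0 FPKM in 5-FU and 0.790 ± 1.10 FPKM in control. The shorter (15721609 to 15738809) was at 12.8 ± 2.30 FPKM in 5-FU and 66.3 ± 14.5 FPKM in control. In H2O2 replicate 2 the longer held 331 and the shorter 12.1 FPKM, while in H2O2 replicates 1 and 3 the shorter held 192 and 221 FPKM and the longer 1.44 and 0 FPKM. The sum under BTD may therefore mix a change of level with the division of reads between these models, which were not separated here.

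Of the gene lists, 6 were called in 5-FU. S phase and replication genes were higher in all 13 measured members (of 22 listed), with a median log2 difference of 0.61 and a camera adjusted p of 6.93e-08, a call that ended at adjusted p = 0.136 with an estimated correlation. Of these, 3 passed over all genes (MCM5, MCM10 and CDC45) and 8 when adjusted over the list alone. DNA repair genes were higher in 17 of 21 members (median 0.49, camera adjusted p = 6.38e-04, and adjusted p = 0.142 with an estimated correlation, which ends the call), with 2 past the threshold over all genes and 8 adjusted over the list alone. BARD1, the partner of BRCA1, rose from 0.561 ± 0.0765 to 1.76 ± 0.169 FPKM (log2 difference 1.09, limma adjusted p = 0.0309), and FANCI, of the Fanconi anaemia pathway, from 33.7 ± 3.05 to 61.7 ± 8.96 FPKM (0.86, adjusted p = 0.0309). G2 and M phase genes were higher in 12 of 13 members (median 0.57, camera adjusted p = 1.49e-04, and adjusted p = 0.136 with an estimated correlation, which ends the call), with 0 past the threshold over all genes by limma and 4 adjusted over the list alone. Those 4 include CDK1, the kinase that drives entry into mitosis, at 6.97 ± 1.48 FPKM in control and 12.7 ± 0.966 FPKM in 5-FU, and BUB1, a spindle checkpoint kinase, at 17.1 ± 0.669 and 24.3 ± 1.46 FPKM. The others, PLK1 (log2 difference 0.53) and TOP2A (0.75), were chosen after their values were seen.

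Genes that p53 activates were higher in 13 of 14 members in 5-FU (median 0.35, camera adjusted p = 0.00336), a call that ended at adjusted p = 0.136 with an estimated correlation. RRM2B, a ribonucleotide reductase subunit induced by p53, rose from 1.15 ± 0.173 to 3.41 ± 0.517 FPKM (log2 difference 1.24, SE 0.23, limma adjusted p = 0.0452) and was the 1 member past the threshold over all genes. Adjusted over the list alone, 4 passed, the others being MDM2, the ligase that limits p53, at 0.89, DDB2, a sensor of DNA damage, at 0.61, and FDXR, a mitochondrial reductase, at 1.02, chosen after their values were seen. Fluoropyrimidine and nucleotide metabolism genes were higher in 13 of 16 members (median 0.35, camera adjusted p = 0.0231, and adjusted p = 0.228 with an estimated correlation). By limma 0 of them passed over all genes and 2 adjusted over the list alone: RRM2, the S phase subunit of ribonucleotide reductase, at 21.1 ± 3.43 and 34.2 ± 5.17 FPKM, and TYMS, the thymidylate synthase that 5-FU inhibits, at 3.38 ± 0.479 and 6.53 ± 0.893 FPKM, the last chosen after its values were seen. The call of that list ended without control replicate 1 (adjusted p = 0.0804), control replicate 2 (0.0531), 5-FU replicate 2 (0.0587) or 5-FU replicate 3 (0.0695) and with both treatment libraries numbered 3 dropped (0.0778), in a range of 0.00722 to 0.0804 over alternatives other than the estimated correlation. Its mean log2 difference, 0.34, was 0.22 without 5-FU replicate 3.

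The host genes of small nucleolar RNAs, lncRNAs whose introns carry guides of ribosomal RNA modification, were lower in 16 of 22 members in 5-FU (median -0.23, camera adjusted p = 0.00161), a call that ended at adjusted p = 0.136 with an estimated correlation. SNHG7, which V29 lists as antisense, and SNHG5 passed over all genes, SNHG5 falling from 27.8 ± 6.45 to 13.4 ± 1.27 FPKM (log2 difference -1.003, SE 0.19, limma adjusted p = 0.0452). Adjusted over the list alone, 4 passed, with SNHG29 at -0.52 and SNHG1 at -0.50, both chosen after their values were seen.

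**Figure D2:**
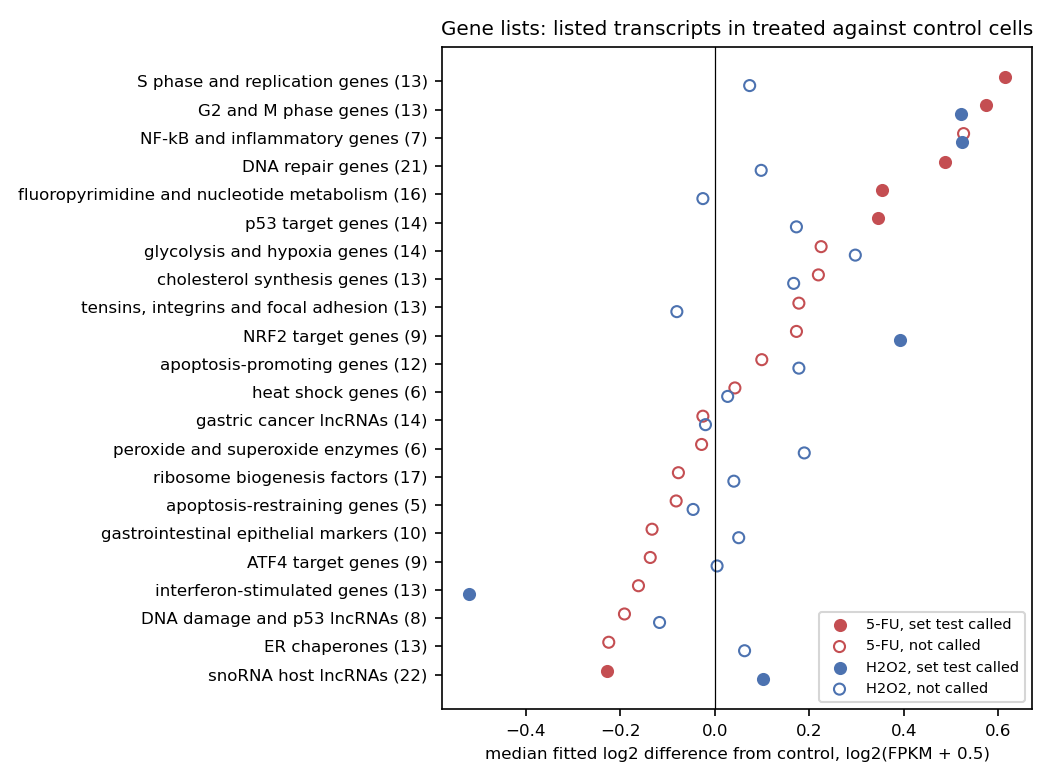
Median fitted log2 difference from control over the tested members of each of 22 gene lists (numbers of genes in brackets), for 5-FU (red) and H2O2 (blue), with filled points where camera called the list. In 5-FU the S phase list has the highest median (0.61) and the small nucleolar RNA hosts the lowest (-0.23), and in H2O2 the interferon-stimulated genes have the lowest (-0.52).

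The other 16 lists were not called in 5-FU. Their camera adjusted p was 0.115 for NF-kB and inflammatory genes, 0.125 for ER chaperones, 0.192 for ATF4 targets, 0.274 for interferon-stimulated genes, 0.302 for DNA damage and p53 lncRNAs, and 0.320 for both NRF2 targets and gastrointestinal epithelial markers. It was 0.461 for ribosome biogenesis factors, 0.585 for gastric cancer lncRNAs, 0.637 for both apoptosis-promoting and cholesterol synthesis genes, 0.668 for heat shock genes and 0.922 for peroxide and superoxide enzymes. It was 0.940 for apoptosis-restraining genes, for glycolysis and hypoxia genes and for tensins, integrins and focal adhesion genes, lists whose median, mean and test differ in sign. KRT8, a keratin of simple epithelia and the most abundant epithelial marker listed, was at 228 ± 57.5 FPKM in control and 103 ± 18.9 FPKM in 5-FU (log2 difference -1.12, limma adjusted p = 0.116). Adjusted over their lists alone, KRT8, KRT19 (-0.65), VEGFA (-0.55) and PHGDH (-0.57) were lower and KRT7 (0.57) higher, as were 4 NF-kB genes, NFKB2 (0.53), NFKBIA (0.53), RELB (1.10) and TNFAIP3 (0.97), a list that fry called (adjusted p = 0.00675). TNFAIP3 was at 0.57 without control replicate 2 (0.57 to 1.28 with 1 library left out). VEGFA ranged from -0.58 to -0.27 over the alternatives, and from -0.58 to -0.51 with 1 library left out. Members outside the naming rule among these were chosen after their values were seen.

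Genes of the lncRNA class supplied 30 of the 77 calls in 5-FU, 14 higher and 16 lower, against 35 higher and 6 lower among transcripts listed under protein-coding genes (Fisher's exact test of direction, two-sided, odds ratio 6.47, p = 7.06e-04). That test treats genes of the same libraries as independent, and the lncRNA calls were 15 higher and 23 lower with median-of-ratios scaling and 14 higher and 10 lower with no filter. They were 17 higher and 24 lower with array weights and, adjusted over lncRNA genes alone, 43 in number, 16 higher and 27 lower. Among those with a symbol, the 3 that rose most at a mean of at least 1 FPKM were GBX2-AS1, from 0.139 ± 0.170 to 1.57 ± 0.598 FPKM (log2 difference 1.69, limma adjusted p = 0.0262), LINC02178, from 0.333 ± 0.130 to 1.87 ± 0.556 FPKM (1.499, adjusted p = 0.0342), and LINC02672, from 0.960 ± 0.0829 to 2.95 ± 0.456 FPKM (1.23, adjusted p = 0.0266). The 3 with a symbol that fell most were H1-10-AS1, from 4.84 ± 0.874 to 1.26 ± 0.271 FPKM (-1.60, adjusted p = 0.0192), ST7-AS1, from 3.37 ± 0.608 to 1.01 ± 0.0843 FPKM (-1.35, adjusted p = 0.0224), and LINC00886, from 2.43 ± 0.375 to 0.681 ± 0.220 FPKM (-1.32, adjusted p = 0.0336). GBX2-AS1, H1-10-AS1 and ST7-AS1 lie opposite other genes, and whether strand entered their quantification is not given in the sources used here. The lncRNA count was 0 without any 1 of the 3 controls or without 5-FU replicate 2 or 3, was 2 without 5-FU replicate 1 and 8 without H2O2 replicate 1.

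The comparison of H2O2 with control asked which transcripts respond to oxidative stress. By limma 0 of 9947 genes passed the threshold, with 902 at an unadjusted p under 0.05 where chance gives 497, a smallest adjusted p of 0.105, and 0 calls also with array weights. Without overlap between groups were 1529 genes, where chance gives 10%. The count became 1 without control replicate 3 or H2O2 replicate 2 and 3 without H2O2 replicate 3.

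Among single transcripts 3 passed in H2O2, and these were chosen after their values were seen. A transcript of the interferon-induced oligoadenylate synthetase gene OAS2 (ENST00000681023, chromosome 12, 113003305 to 113011138), fell from 21.3 ± 1.39 to 3.05 ± 1.18 FPKM (log2 difference -2.66, SE 0.25, limma adjusted p = 0.0151). A retained-intron transcript of the meiosis regulator MARF1 (ENST00000551579) rose from 0.248 ± 0.0475 to 2.27 ± 0.397 FPKM (1.88, SE 0.19, adjusted p = 0.0242). A transcript of CYP1B1-AS1, antisense to the CYP1B1 gene (ENST00000627172), was listed at 0 in all 3 controls, with means of 2.14 ± 0.467 FPKM in H2O2 (adjusted p = 0.0151) and 1.93 ± 0.497 FPKM in 5-FU, where it was the 1 transcript called (adjusted p = 0.0420). In H2O2 the transcript count was 8, 5 and 1 without control replicates 1, 2 and 3, was 5, 5 and 8 without the 5-FU replicates in order, and 0, 7 and 7 without the H2O2 replicates. In 5-FU it was 0, 2 and 3 without the controls, 0, 2 and 4 without the 5-FU replicates, and 6 and 2 without H2O2 replicates 2 and 3. At an unadjusted p under 0.05 were 1719 and 2353 of 22618 transcripts, where chance gives 1131.

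Targets of NRF2 were among the 5 lists called in H2O2. NRF2 target genes, which encode antioxidant enzymes, were higher in 8 of 9 measured members (of 22 listed), with a median log2 difference of 0.39 and a camera adjusted p of 6.38e-04, a call that ended at adjusted p = 0.136 with an estimated correlation. By limma 0 of them passed over all genes, while 4 passed adjusted over the list alone. These were AKR1C2, an aldo-keto reductase, at 2.06 ± 0.532 FPKM in control and 7.16 ± 1.61 FPKM in H2O2 (1.58), TXNRD1, thioredoxin reductase, at 10.6 ± 1.21 and 18.2 ± 3.13 FPKM (0.74), PGD, of the pentose phosphate pathway, at 1.65 ± 0.392 and 3.09 ± 0.702 FPKM (0.74), and GCLC, the catalytic subunit of glutathione synthesis, at 11.8 ± 1.48 and 32.6 ± 15.0 FPKM (1.31). They were chosen after their values were seen. The 2 most abundant members were FTH1, the ferritin heavy chain, at 219 ± 58.7 and 263 ± 19.7 FPKM, and TKT, transketolase, at 28.2 ± 2.53 and 34.6 ± 5.79 FPKM, neither past a threshold. FTH1 was at 0.29 on the log2 scale, but at 0.13 without control replicate 2 and 0.496 without control replicate 3, and TKT at 0.28, but at 0.42 without H2O2 replicate 1 and 0.18 without H2O2 replicate 2.

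Interferon-stimulated genes were lower in 11 of 13 members in H2O2 (median -0.52, camera adjusted p = 4.61e-06), a call that ended at adjusted p = 0.136 with an estimated correlation. OAS2 was at 26.2 ± 2.16 FPKM in control and 10.5 ± 3.13 FPKM in H2O2 (log2 difference -1.32). Its transcript ENST00000681023 alone fell further, from 21.3 ± 1.39 to 3.05 ± 1.18 FPKM. The other listed OAS2 transcripts together were therefore higher in H2O2. Division of reads between models may enter the gene value and was not tested. By limma 0 members passed over all genes and 6 adjusted over the list alone, OAS2 among them. RSAD2 (-0.91), OASL (-0.72), IFI44L (-0.76) and the RNA sensor RIGI (-0.70) also passed over the list alone and were chosen after their values were seen. G2 and M phase genes were higher in all 13 members (median 0.52, camera adjusted p = 3.76e-06, and adjusted p = 0.136 with an estimated correlation, which ends the call), 0 over all genes and 2 adjusted over the list alone: BUB1, at 17.1 ± 0.669 and 27.2 ± 3.97 FPKM (0.65), and PLK1 (0.75), chosen after its values were seen.

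NF-kB and inflammatory genes were higher in 6 of 7 measured members (of 18 listed) in H2O2 (median 0.52, camera adjusted p = 0.0144, and adjusted p = 0.136 with an estimated correlation, which ends the call), with 0 past the threshold over all genes by limma and 2 adjusted over the list alone. The median of this list was 0.53 in 5-FU, where camera did not call it. Between the treatments it was not called either (median -0.05, camera adjusted p = 0.730), so the rise is not particular to H2O2. NFKBIA, the inhibitor that NF-kB induces, was at 3.31 ± 0.533 FPKM in control and 6.16 ± 0.408 FPKM in H2O2 (log2 difference 0.82), and RELB, an NF-kB subunit chosen after its values were seen, at 0.581 ± 0.537 and 1.97 ± 0.616 FPKM. Host genes of small nucleolar RNAs were higher in 16 of 22 members (median 0.10, camera adjusted p = 0.0212, and adjusted p = 0.142 with an estimated correlation, which ends the call), 0 over all genes and 2 adjusted over the list alone, SNHG15 at 1.06 and SNHG16 at 0.99, chosen after their values were seen. GAS5, of the same list, was at 120 ± 7.01 and 148 ± 3.17 FPKM. The NF-kB call ended without H2O2 replicate 1 (adjusted p = 0.108) and without a filter (0.122, with the mean log2 difference going from 0.44 to 0.22), in a range of 9.07e-04 to 0.122. Over the alternatives the mean of that list ranged from 0.22 to 0.68. The host gene call ended without control replicate 2 (0.102) or H2O2 replicate 2 (0.0716), and with common-total (0.0524) or quantile scaling (0.125), in a range of 0.0111 to 0.125.

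The other 17 lists were not called in H2O2. The camera adjusted p was 0.0744 for glycolysis and hypoxia genes, 0.158 for p53 targets, 0.427 for ribosome biogenesis factors, 0.444 for DNA damage and p53 lncRNAs and 0.488 for peroxide and superoxide enzymes. It was 0.532 for cholesterol synthesis genes and for tensins, integrins and focal adhesion genes, 0.537 for apoptosis-promoting and 0.637 for apoptosis-restraining genes, 0.620 for gastric cancer lncRNAs, 0.847 for gastrointestinal epithelial markers and 0.861 for heat shock genes. It was 0.940 for ATF4 targets, 0.966 for S phase genes, 0.972 for DNA repair genes, and 0.979 for ER chaperones and for fluoropyrimidine metabolism genes, with the sign of the test unlike that of the median for ATF4 targets and fluoropyrimidine metabolism. Adjusted over its list alone, KRT7 was higher (log2 difference 0.77), a gene chosen after its values were seen. Of the remaining lists, no member of metallothioneins, replication-dependent histones, blood cell markers or mitochondrially encoded mRNAs reached the filter. Of AP-1 and immediate early genes, KLF4 and FOSB did, with limma adjusted p of 0.318 and 0.574 in 5-FU, and of fibroblast markers COL1A1 alone, at 0.374 ± 0.140 FPKM in control.

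**Figure D3:**
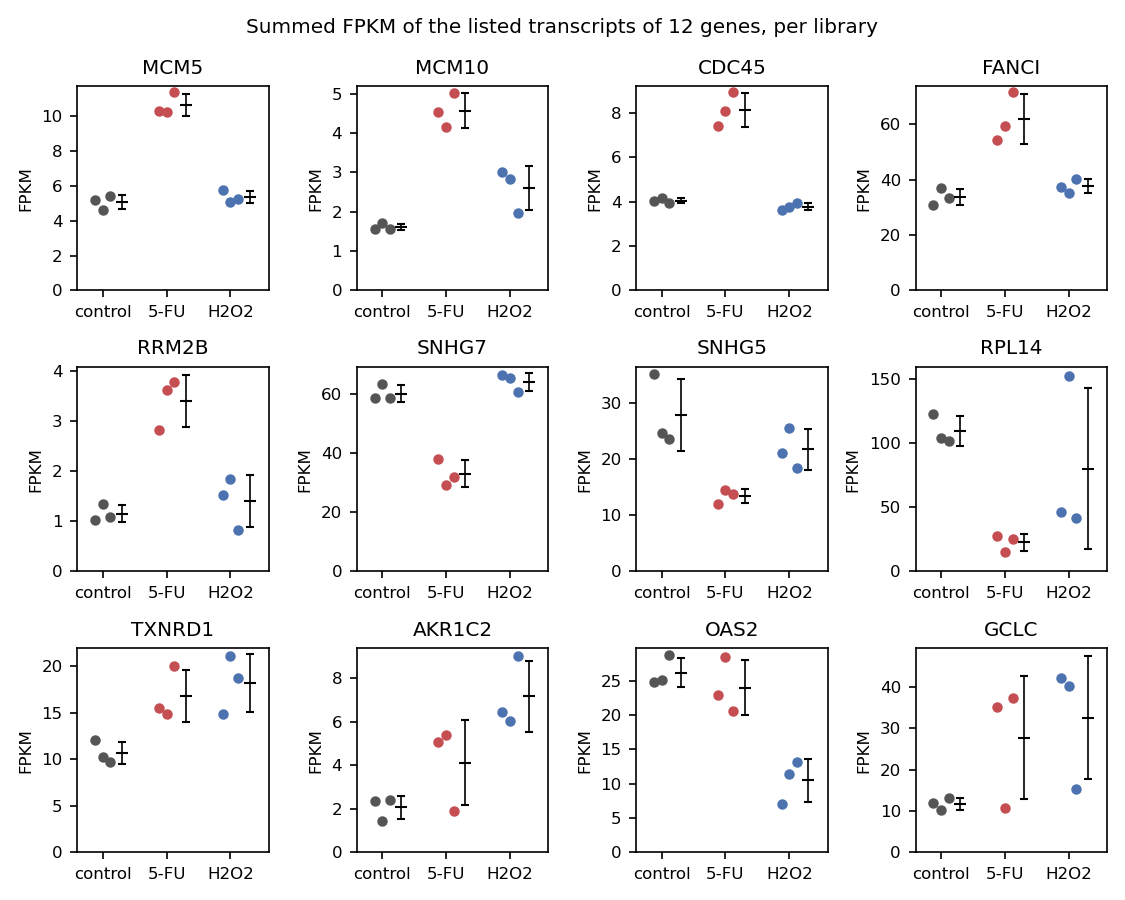
Summed FPKM of the listed transcripts of 12 genes in each library (points) with the mean and SD of 3 replicates beside them (bars), genes chosen after their values were seen. MCM5 lies near 5.08 FPKM in control and 10.7 FPKM in 5-FU, and OAS2 near 26.2 FPKM in control and 10.5 FPKM in H2O2. The fall of OAS2 lay in its transcript ENST00000681023.

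The direct comparison of 5-FU with H2O2 tested whether the treatments differ. CDC45 was higher in 5-FU than in H2O2, at 8.14 ± 0.767 and 3.77 ± 0.164 FPKM (log2 difference 1.01, SE 0.14, limma adjusted p = 0.0487), as was LINC02672 (1.46, SE 0.20). PIF1 (-1.66, SE 0.21), H1-10-AS1 (-1.48, SE 0.20) and SNHG7 (-0.95, SE 0.13) were lower. With 2 more outside the naming rule, AGBL1 and an assembled gene on an unplaced scaffold, chosen after their values were seen, 7 genes passed, 3 higher and 4 lower in 5-FU, each with an adjusted p of 0.0487. The number at an unadjusted p under 0.05 was 1149, where chance gives 497. The count was 0 without any 1 of the controls, without 5-FU replicate 2 or 3, or without H2O2 replicate 1 or 2, was 2 without 5-FU replicate 1 and 4 without H2O2 replicate 3. Of single transcripts 3 passed, chosen after their values were seen: the OAS2 transcript ENST00000681023, higher in 5-FU, and transcripts of TTLL3 and GMDS-DT, lower, with log2 differences of 2.598, -2.17 and -1.80.

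Of the lists, 7 differed between the treatments, in tests added after the data were seen. S phase genes were higher in 5-FU than in H2O2 in 12 of 13 members (median 0.72, camera adjusted p = 2.72e-10, and adjusted p = 0.0192 with an estimated correlation). Of these, 1 passed over all genes and 9 adjusted over the list alone, MCM5 among them (0.93). Host genes of small nucleolar RNAs were lower in 20 of 22 members (median -0.50, adjusted p = 5.18e-10, and 0.0137 with an estimated correlation), 1 over all genes and 10 adjusted over the list alone, with GAS5 at -0.54 and SNHG15 at -0.86. Over the alternatives GAS5 ranged from -0.55 to -0.27, and from -0.55 to -0.52 with 1 library left out. DNA repair genes were higher in 17 of 21 members (median 0.40, adjusted p = 4.23e-05), 0 over all genes by limma and 7 adjusted over the list alone, and adjusted p = 0.139 with an estimated correlation.

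Smaller differences between the treatments covered 4 lists. Interferon-stimulated genes were higher in 5-FU in 11 of 13 members (median 0.31, camera adjusted p = 0.00366, and 0.219 with an estimated correlation), a call that also ended with fry (0.109) and with both treatment libraries numbered 3 dropped (0.109). Fluoropyrimidine metabolism genes were higher in 13 of 16 (median 0.24, adjusted p = 0.0172, and 0.217), TYMS at 1.001. Glycolysis and hypoxia genes were lower in 11 of 14 (median -0.23, adjusted p = 0.0285, and 0.366) and NRF2 targets in 9 of 9 (median -0.29, adjusted p = 0.0438, and 0.219). Of these members 0 passed over all genes by limma, and 3, 2, 0 and 0 passed adjusted over the list alone. The fluoropyrimidine call ended without 5-FU replicate 3 (0.0725) or H2O2 replicate 3 (0.0642), with fry (0.109) and with both treatment libraries numbered 3 dropped (0.161). The NRF2 call ended without 5-FU replicate 2 (0.235) or H2O2 replicate 3 (0.122), with quantile scaling (0.0731), with fry (0.128) and with both libraries numbered 3 dropped (0.0830). The glycolysis call ended without 5-FU replicate 2 (0.0938), 5-FU replicate 3 (0.127), H2O2 replicate 1 (0.0587) or H2O2 replicate 3 (0.337), with quantile scaling (0.258), array weights (0.0531) or fry (0.320), and with both libraries numbered 3 dropped (0.689). The mean log2 difference of the fluoropyrimidine list, 0.26, was 0.14 without 5-FU replicate 3 and 0.09 with both dropped, and that of interferon-stimulated genes, 0.34, was 0.19 with both dropped. The NRF2 mean, -0.29, was -0.18 without 5-FU replicate 2. The glycolysis mean, -0.23, was -0.37 without H2O2 replicate 2, -0.08 without H2O2 replicate 3 and -0.03 with both dropped. The remaining 15 lists had an adjusted p from 0.0504 to 0.948.

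Differences from control in the 2 treatments were also set side by side. No gene was called the same way by both, a count of 0 that was fixed by the 0 genes limma called in H2O2. It became 1 without control replicate 3 and 1 without H2O2 replicate 2. At an unadjusted p under 0.05 in both, 223 genes were higher and 139 lower in both treatments and 3 moved in opposite directions. Independent lists would share 47.5 and 24.3 genes, and unchanged groups simulated against the same controls shared 112 genes (88 to 140 in 100 simulations) against 362 observed. Across genes, which are not independent replicates, the differences correlated at 0.526, against a simulated 0.50 (0.475 to 0.525), with a covariance of 0.0763 against 0.0388 (0.0359 to 0.0420). The same sign held in 68.8% of genes, against 66.6% simulated. Shared controls add the same covariance with or without effects, so the difference of 0.0375 estimates what the 2 treatments have in common against control. An offset common to all 3 control libraries would add to it too, and the spread between those libraries cannot show one. The difference is therefore not assigned to a common effect of treatment. For the number of shared genes the 3 controls cannot be split into separate groups of 2, and how much of that excess comes from the shared controls is open.

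The genes in the title of the study were examined last. TNS4, which encodes a focal adhesion protein of the tensin family (ENSG00000131746, chromosome 17, 40475828 to 40480875, retained-intron transcripts), was at 4.29 ± 2.24 FPKM in control, 5.55 ± 1.28 FPKM in 5-FU and 3.06 ± 0.464 FPKM in H2O2 (SD, n = 3). The differences from control, 0.42 (SE 0.30, limma adjusted p = 0.540, exact permutation p = 0.4) and -0.34 (SE 0.30, adjusted p = 0.761, exact permutation p = 0.5), were within the spread of the replicates. Between treatments the 3 5-FU libraries all lay above the 3 H2O2 libraries, but the difference did not pass the threshold (0.75, SE 0.30, limma adjusted p = 0.364). Control replicate 3 held 3.23 FPKM of the transcript TNS4-202, against 0.302 and 0.186 FPKM in the other controls. Without it the differences were 0.77 and 0.02, so the direction in H2O2 depends on it, and they ranged over 0.16 to 0.77 and -0.59 to 0.02 when 1 library was left out. The other transcript, TNS4-203, was at 3.05 ± 0.571, 5.34 ± 1.29 and 2.85 ± 0.550 FPKM (5-FU against control 0.71, limma adjusted p = 0.330). For this transcript the 3 5-FU libraries all lay above the 3 controls (limma unadjusted p = 0.0117), a separation that chance gives in 10% of cases. TNS4 was examined because the title names it, and how the study chose it is not given in the sources used here, so its values are not taken as independent evidence.

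No gene of the table carried the name FUAT1. TNFRSF10A-AS1, tried as its possible database symbol, had 1 transcript (chromosome 8, 23189279 to 23190675), which is listed at 0 in all 9 libraries. Nearby, the death receptor gene TNFRSF10B was at 26.2 ± 10.2 FPKM in control, 28.2 ± 8.85 FPKM in 5-FU and 24.9 ± 3.58 FPKM in H2O2 (limma adjusted p = 0.881 and 0.992, exact permutation p = 1 for both), with log2 differences of -0.10 to 0.42 and -0.18 to 0.28 when 1 library was left out. TNFRSF10A, a related receptor gene, stayed under the filter at 0.284 ± 0.0597, 0.318 ± 0.0658 and 0.414 ± 0.0919 FPKM (exact permutation p = 0.7 and 0.2). TNFRSF10A-DT, a divergent lncRNA gene named after its values were seen, was at 4.96 ± 1.001, 3.71 ± 0.472 and 3.77 ± 0.700 FPKM (log2 differences -0.37 and -0.35, or -0.22 and -0.21 without control replicate 3, limma adjusted p = 0.401 and 0.612). Its exact permutation p was 0.1, the smallest that 3 against 3 libraries can give, and 0.2. Its transcripts moved in opposite ways in 5-FU. TNFRSF10A-DT-201 went from 2.23 ± 1.25 to 0.806 ± 0.338 FPKM and TNFRSF10A-DT-204 from 1.86 ± 0.0627 to 2.44 ± 0.242 FPKM (limma adjusted p = 0.407 and 0.552). Division of reads between them was not tested. Another entry of the same symbol (ENSG00000250714) stayed under the filter, at 0.210 ± 0.0715 FPKM in control.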

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

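Alternatives that leave out assembled transcripts, weight the libraries or drop both treatment libraries numbered 3 were chosen after the results were seen. The 7 genes below stood out because limma's test of 5-FU against H2O2 placed their responses to the treatments apart, each with an adjusted p of 0.0487.

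CDC45, of the replicative helicase, differed by 1.01 on the log2 scale (5-FU minus H2O2), at 0.92 in 5-FU and -0.09 in H2O2 against control. LINC02672, a lincRNA gene, differed by 1.46, at 1.23 and -0.23. PIF1, a DNA helicase gene, differed by -1.66, at -1.36 and 0.30. SNHG7, a host of small nucleolar RNAs, differed by -0.95, at -0.86 and 0.09. H1-10-AS1, an antisense lncRNA gene, differed by -1.48, at -1.60 and -0.12. AGBL1, a carboxypeptidase gene, differed by -1.91, at -1.80 and 0.11, from means of 1.42 ± 0.373 FPKM in control, 0.0486 ± 0.0675 FPKM in 5-FU and 1.58 ± 0.439 FPKM in H2O2. XLOC_061514, an assembled gene on the unplaced scaffold KI270544.1, differed by 1.07, at 0.84 and -0.23.

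These calls sit at the edge of the threshold: 0 genes passed with the assembled transcripts left out and 3, all among the 7, with array weights. With both treatment libraries numbered 3 dropped 4 genes passed, and with 1 library left out 0 to 4 did, with 0 of the 7 among them. Of the 10 splits of the 6 libraries, 1, the real one, gave 7 genes and the highest other gave 2, and 10 splits are too few for a share under 0.05. The other splits mix the 2 treatments, so a difference between them would enter the spread and lower those counts.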

How the results depend on the processing

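Leaving out assembled transcripts, array weights, dropping both treatment libraries numbered 3, adjusting over lncRNA genes alone and all list tests in 5-FU against H2O2 were chosen after the results were seen. All 77 genes called in 5-FU kept their sign and an unadjusted p under 0.05 under each alternative that gave them a value (70 genes with assembled transcripts left out, 74 with a filter at 1 FPKM). These genes were picked for small p-values on the same libraries, so this was nearly fixed in advance and is not independent support for them. Their adjusted p was less steady. In the contrasts with control, the S phase, G2 and M phase, DNA repair, p53, NRF2 and interferon lists and the small nucleolar RNA hosts in 5-FU kept their calls under every alternative except the estimated correlation. Unknown depth leaves genes with low values without a counting error. Where no reason is given for the changes below, the cause was not tested.

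For 5-FU genes (77), the count was 48 with no filter, 21 in a fit on the 2 groups alone, which has fewer libraries, and 3 with the third treatment libraries dropped. For lncRNA genes in 5-FU (30) it was 6 in the fit on 2 groups and 0 with the third libraries dropped. For H2O2 genes (0) it was 6 with the third libraries dropped. For 5-FU against H2O2 (7) it was 0 with no filter, in the fit on 2 groups and without assembled transcripts, 3 with array weights and 4 with the third libraries dropped. For 5-FU transcripts (1) it was 3 with a pseudocount of 0.1, 0 with 1, 17 with no filter, 0 with a filter at 1 FPKM, 3 with median-of-ratios, 3 with common-total and 4 with quantile scaling, 5 in the fit on 2 groups, 3 with robust moderation, 3 without assembled transcripts, 3 with array weights and 2 with the third libraries dropped. For H2O2 transcripts (3) it was 5 with a pseudocount of 0.1, 7 with no filter, 9 in the fit on 2 groups, 5 with robust moderation, 7 with array weights and 14 with the third libraries dropped. Lists called fell from 6 to 0 in 5-FU and from 5 to 0 in H2O2 with an estimated correlation, and from 7 to 2 in 5-FU against H2O2, where fry called 3 and dropping the third libraries left 3.

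With a single library left out, which leaves 1 group with 2 libraries, counts ranged over 0 to 88 for 5-FU genes, 0 to 33 for lncRNA genes in 5-FU, 0 to 0 for lncRNA genes in H2O2, 0 to 3 for H2O2 genes, 0 to 4 for 5-FU against H2O2, 0 to 6 for 5-FU transcripts, 0 to 8 for H2O2 transcripts and 0 to 1 for genes called the same way by both. Lists ranged over 5 to 6 in 5-FU, 4 to 6 in H2O2 and 4 to 9 between treatments. The TNS4 difference ranged over 0.16 to 0.77 in 5-FU and -0.59 to 0.0186 in H2O2, the sign turning without control replicate 3. TNFRSF10B, near 0, ranged over -0.10 to 0.42 in 5-FU and -0.18 to 0.28 in H2O2. Its sign turned in 5-FU without control replicate 2 (-0.01), control replicate 3 (-0.04) or 5-FU replicate 3 (-0.10) and with the third libraries dropped (-0.10), and in H2O2 without control replicate 1 (0.28) or H2O2 replicate 1 (0.09).

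With the replicate number as a block, 0 genes were called in 5-FU, 0 lncRNA genes in 5-FU, 0 genes in 5-FU against H2O2 and 0 transcripts in 5-FU or H2O2. Any pairing by number was weak: residuals of same-numbered libraries correlated at -0.036 to 0.08, with 0 of 9 pairs over 0.1, against -0.082 to 0.047 for other pairs. Between 5-FU and H2O2, however, the same-numbered pairs, at 0.08, 0.016 and 0.062, all lay above the other pairs, at -0.082 to 0.012. A weak pairing of the treatment libraries therefore stays open.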

Other observations

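The test of ribosomal protein genes, the tests of gene classes, the neighbour count and the list tests between treatments were chosen after the results were seen. Transcripts listed under ribosomal protein genes, 62 of which were tested, were lower in 46 in 5-FU, with a median log2 difference of -0.24 against 0.10 in H2O2 (camera p = 2.94e-05 in 5-FU, 0.0270 with an estimated correlation, and 0.581 in H2O2). RPL14 was the 1 of these genes called. Antisense lncRNA genes by V29 were lower in 5-FU in 698 of 1023 (median -0.18, camera adjusted p = 3.85e-08, and adjusted p = 0.0438 with an estimated correlation), with 10 called lower and 4 higher. In H2O2 610 of 1023 were lower (median -0.08, adjusted p = 8.45e-04, and 0.253 with an estimated correlation). Bidirectional promoter lncRNA genes were lower in 18 of 25 in 5-FU (median -0.26, adjusted p = 0.00296, and 0.0438 with an estimated correlation). Other classes moved in 5-FU too, with calls that ended with an estimated correlation: lincRNA genes were lower in 497 of 830 (adjusted p = 0.00690, and 0.125), processed transcripts in 107 of 193 (0.0252, and 0.125), and genes listed as protein-coding were higher in 4004 of 6700 (4.86e-05, and 0.104). The protein-coding median, 0.08, was 0.04 with quantile and 0.05 with median-of-ratios scaling. That class was higher in H2O2 too, in 3905 of 6700 (camera adjusted p = 0.00713, and 0.433 with an estimated correlation).

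Among genes called in 5-FU, 2 pairs lay within 10 kb of each other with the same direction, against a mean of 0.104 and a highest of 1 in 1000 random draws. UFD1, which helps to extract ubiquitinated proteins, and CDC45 both rose and lie 551 bases apart on chromosome 22. ADAMTSL4-AS2 and ADAMTSL4-AS1 lie 2478 bases apart on chromosome 1. These genes other than CDC45 were chosen after their values were seen.

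Replication genes were higher in 5-FU as a list, with a median of 0.61, though the call ended at adjusted p = 0.136 with an estimated correlation. The tables argue against a general rise of transcripts under protein-coding genes as the whole cause, since 10000 matched random lists had a median of 0.07. The list median lay at percentile 100 of them. That percentile repeats the comparison with other genes that camera made and leaves out correlation within the list, so it is not further support. The tables also argue against 5-FU replicate 3 as the whole cause, since the median stayed at 0.56 without it. Library scaling is argued against too, since the smaller median of median-of-ratios and quantile scaling was 0.54. G2 and M phase genes were higher in 5-FU too, in 12 of 13 members with a median of 0.57, so against control the rise was not particular to S phase genes. In H2O2 the G2 and M phase median was 0.52 and the S phase median 0.07. Between the treatments the S phase list was higher in 5-FU (median 0.72), while the G2 and M phase list was not called (median -0.08, camera adjusted p = 0.948). A candidate explanation is a larger share of cells in S phase under 5-FU, a hypothesis found on these libraries and not tested here. DNA content per cell would measure that share, but not whether it accounts for the rise. Whether the mRNAs of these genes follow their listed transcripts was not analysed here.

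Host genes of small nucleolar RNAs were lower in 5-FU, with a median of -0.23, though the call ended at adjusted p = 0.136 with an estimated correlation. Without 5-FU replicate 3 the median was -0.23 too, which argues against that library as the cause. A general fall of lncRNA genes stays open, since the list median lay at percentile 5.31 of matched random lncRNA lists, whose median was -0.08. The host genes may share their fall with ribosomal protein genes, whose median was -0.24. Other causes were not tested, and no biological explanation was tested.

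Antisense lncRNA genes were lower in 5-FU, with a median of -0.18. Low expression and the pseudocount are argued against, since protein-coding genes matched on expression were not lower, with a median of 0.07 over 10000 random sets. The antisense median lay at percentile 0 of those sets. That percentile was nearly fixed by the shift of the whole protein-coding class (median 0.08) and is not further support. Also argued against is 5-FU replicate 3 as the cause, since the median was -0.17 without it. Reads of the gene on the other strand cannot be told apart: over 146 pairs the median of the named genes was 0.0597 and the correlation of the 2 differences across pairs was 0.013, at percentile 55.7 of shuffled pairs. A median at or above 0 had been taken beforehand as evidence against this, but the values under the named genes are mostly retained-intron transcripts, not the mRNAs that would supply such reads.

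Each count was compared with other splits of the 6 libraries of its groups, of which there are 10, too few for a share under 0.05. Every split but the real one mixes the 2 groups, so a difference between them would enter the spread and lower the count. The counts of those splits are therefore no reference for libraries without an effect. In 5-FU against control, 1 split, the real one, reached 77 genes (highest other 1), 1 reached 30 lncRNA genes (highest other 0) and 1 reached 6 lists (highest other 4), while 7 splits reached 1 transcript (highest other 6). In H2O2 against control, 10 splits reached 0 genes (highest other 2), 10 reached 0 lncRNA genes (highest other 1), 1 reached 5 lists (highest other 3) and 6 reached 3 transcripts (highest other 8). Every split reaches a count of 0, so the comparisons for genes and lncRNA genes in H2O2 decide nothing. Between treatments 1 split reached 7 lists (highest other 6).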
